A study of Pseudomonas aeruginosa with 4 samples.

How the data were processed

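Transcripts of Pseudomonas aeruginosa PAO1 were measured on 4 Affymetrix GeneChips of the type Pae_G1a, 2 for untreated cultures and 2 for cultures grown with azithromycin at 2 µg/ml. Per the labels, bacteria grew in brain heart infusion medium with shaking, 4 cultures of 150 ml per condition, and 10 ml of each was sampled in early stationary phase. RNA was isolated with hot phenol, RNA from 2 cultures was combined for each chip, and 10 µg was turned into cDNA carrying a biotin end label. The replicates are therefore pools, n = 2 per condition.

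The deposited table holds 1 intensity per probe set and array on a linear scale, a signal with 1 value for each of 5896 probe sets. The software and the scaling method behind it are not given in the sources used here. Its means trimmed by 2% at each end lay between 150.1 and 150.2 on the 4 arrays, within the tolerance of 5% fixed beforehand, so the deposited intensities were taken as scaled and used as they stood. Detection calls were not used here. The deposited instrument files give other information, settings of the fluidics station and scanner, per the file headers. They record 1 hybridisation date and 1 scan date for all arrays and 4 fluidics modules, 1 per array, so no date could serve as a block.

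Probe sets were sorted by their identifiers into 5545 for PAO1 genes, 199 for intergenic regions, 138 for genes of other strains and for ribosomal and transfer RNA, and 14 controls. Each PAO1 gene had 1 probe set, and 94 of these carry the suffix s, i, r or f. Some of these suffixes mark probes that may match more than a single transcript. Of the genes, 5504 matched a locus tag of the assembly ASM676v1 and 41 did not. That assembly served for names and for which genes neighbour each other, and no coordinates are given because the files name no build. In the platform annotation 5500 probe sets have 1 gene symbol, 0 have several and 396 have none. Symbols are those of the assembly ASM676v1, or of the array design where the assembly gives none, and genes without a symbol go by locus tag.

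The 5545 genes were tested on log2 values with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), azithromycin minus untreated, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 23.1. A signal at or below the highest control probe set of its array was taken as control level. That control was 61.4 and 48.6 in the untreated arrays but 10.7 and 29.2 in the azithromycin arrays. A dim signal therefore counts as control level more readily in untreated arrays. Where both arrays of a group were at that level, the fold is given as "at least", from the mean log2 of the brighter group against the mean of, per array, the higher of that control and the gene's own signal. The number of arrays limits the precision.

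Before the data were examined, 25 gene lists were fixed by locus tag, 511 genes in all with no gene in more than a single list, of which 502 were measured. They cover quorum sensing regulators, quorum-controlled exoproducts, phenazines, alkyl quinolones (PQS), flagellum and chemotaxis, type IV pili, ribosomal proteins, translation factors, alginate, type III secretion, type VI secretion (HSI-I), type II secretion (Xcp), pyoverdine, pyochelin, chaperones and proteases, the oxidative stress response, RND efflux pumps, denitrification with arginine fermentation, pyocins, the SOS response, Psl and Pel polysaccharides, PhoPQ with PmrAB and arn, NADH dehydrogenase with ATP synthase, the TCA cycle and Gac/Rsm signalling. The list of ribosomal proteins holds PA4672, a peptidyl-tRNA hydrolase gene, by mistake for PA4671, the gene of protein L25; it was kept as fixed. Not measured were 7 of 17 phenazine genes, 1 translation factor and 1 gene of the TCA cycle. Lists were tested with camera of limma (preset correlation 0.01, two-sided, adjusted over the lists), and members past the threshold were counted after adjustment over all genes and over the list alone.

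The genes named were set by a rule fixed at the same time. It takes, per direction, the 10 genes with the largest fold among those past the threshold whose arrays of the 2 groups do not overlap and whose brighter group is at or above the median signal. It adds the 3 members with the smallest p of each list past the list test, and always lasI, lasR, rhlI, rhlR, rsaL, lasB, aprA, rhlA, lecA, fliC, pqsA, mexX, rpoS and algD. This gave 47 genes. Other list members past the threshold are also named in their groups, chosen after their values were seen.

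Alternatives fixed beforehand were quantile normalization, centring each array on its median, an offset of the 25th percentile of signal before the log, leaving out genes under the 20th or the 40th percentile of signal, a variance prior without a trend, a robust prior and leaving out each array in turn. When an array was left out, the lone array of that group was assumed to vary like the pair in the other. For the lists, the alternatives were camera with an estimated correlation, camera on ranks, and fry. Camera with an estimated correlation uses the 2 residual degrees of freedom, so few lists of any correlation could pass it after adjustment. The RND pump list had an estimated correlation of -0.034, below the preset, and its camera p still rose from 0.00789 to 0.0998. A block for pairs of arrays of like spread and the ribosomal list with PA4671 in place of PA4672 were added after seeing the data. The variance prior of the block fit had infinite degrees of freedom, so a gene's own spread did not enter its gene calls.

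The procedure was tested on simulated data made from these 5545 genes, in 20 runs with 200 changed genes each. It recovered 0.386% of 2-fold, 12.8% of 4-fold and 35.1% of 8-fold changes, and among genes at or above the median signal 0.463%, 21.2% and 52.4%. False calls made up 6.57% of all calls. Unchanged lists were called in 0.2% of cases, and lists shifted by 1 log2 unit in 100% of cases. The simulated genes varied independently, while the estimated correlation was 0.23 for the type III secretion list and 0.57 for the ribosomal list. These rates for lists therefore do not carry over to the real lists. The simulated arrays also had no differences in spread, and their variances came from the fitted prior. The recovery and false-call rates for genes therefore need not hold for the real calls either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.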

Results

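Transcript levels of Pseudomonas aeruginosa PAO1, the common laboratory strain of an opportunistic pathogen, were compared between cultures grown with 2 µg/ml azithromycin, a macrolide antibiotic that binds the bacterial ribosome, and untreated cultures. All were sampled in early stationary phase at 37 °C. Each array holds RNA pooled from 2 of the 4 cultures of a condition, so n = 2 pools per group. In the p-values and SE the pools supply 2 degrees of freedom, and 23.1 come from a prior shared by genes of like signal. For the top 5% of genes by signal the median SE was 0.434 as deposited and 0.254 after quantile normalization, with 66 and 140 calls. Not passing as deposited therefore says little for genes that bright. Arrays are called untreated replicates 1 and 2 and azithromycin replicates 3 and 4. The median signal of PAO1 genes was 116 and 134 in the untreated arrays and 122 and 98.3 in the azithromycin arrays. Errors are SE of the log2 difference from limma, or SD of signals.

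The question was which transcripts differ in bacteria grown with azithromycin. Genes of type III secretion, the needle apparatus that delivers effector proteins into host cells, rose: 21 of 40 measured members passed the test and all 21 were higher, with exoT up 13.9-fold. The list of ribosomal protein genes was higher as a group by camera with its preset correlation, 9 of 54 members past the test. With an estimated correlation, a test with only 2 degrees of freedom, neither list passed (adjusted p = 0.726 for type III secretion and adjusted p = 0.835 for ribosomal proteins). The ribosomal list was also weaker without untreated replicate 2, its shift relative to all genes going from 0.84 to 0.39 log2 units. The gene infA, encoding translation initiation factor IF-1, rose 16.4-fold, with 1 untreated array at control level. The quorum sensing genes lasR and lasI fell, as did aprA and lasA, which encode secreted proteases, and katA, the main catalase gene. Median centring ended the calls of lasR, lasI and lasA but not those of aprA and katA. For aprA, 1 azithromycin array was at control level. All 4 genes of the mexGHI-opmD efflux operon fell, while pqsA, in the pathway to the signal molecule PQS, rose.

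Within type III secretion, pcrV, encoding the needle tip protein, had a signal of 26.3 ± 28.9 (SD) in untreated and 1953 ± 868 in azithromycin cultures. Both untreated arrays were at control level, so the rise was at least 33.9-fold (adjusted p = 1.41e-07). The effector genes exoT (log2 3.79 ± 0.38, adjusted p = 4.32e-07), exoY (4.26 ± 0.53, adjusted p = 7.05e-06) and exoS (3.08 ± 0.45, adjusted p = 5.43e-05) rose. So did pcrH, a chaperone gene of the translocators (4.08 ± 0.38, adjusted p = 1.41e-07), and PA3842, next to exoS (3.90 ± 0.36, adjusted p = 1.41e-07). PA1699 (at least 3.91-fold, adjusted p = 0.0451) and pscB (3.96 ± 0.89, adjusted p = 0.00720) rose as well. Over the alternative fits their log2 differences varied widely, from 1.87 to 4.83 for PA1699 and from 2.05 to 5.47 for pscB. Of the 10 genes that the naming rule took by fitted rise, 5 had 1 untreated array at control level (exoY, pcrH, pscB, infA and PA2901). Both untreated arrays were at that level for pcrV and PA1699, so the rank of these 2 is not measured. The translocator genes popB and popD rose by log2 2.47 ± 0.46 and 2.23 ± 0.40, while exsA, encoding the activator of the system, had log2 1.00 ± 0.37 at adjusted p = 0.172 and did not pass. The remaining members past the test were exsB, exsC, exsD, PA1711, popN, PA1700, PA1701, pcrG, pscC, pscO and pscP.

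The type III secretion list lay 1.92 log2 units above the median of all genes (camera adjusted p = 5.66e-32). With an estimated correlation the camera p was 0.0450 unadjusted and 0.726 adjusted. Adjusted over the list alone, 24 members rose and 0 fell, and 25 rises and 0 falls had an unadjusted limma p under 0.05. Leaving out azithromycin replicate 4 left 7 members past the test and leaving out azithromycin replicate 3 left 13. The call for pcrV was lost without azithromycin replicate 4 (adjusted p = 0.0654) and with the robust prior (adjusted p = 0.177). That for exoY was lost without azithromycin replicate 3 (adjusted p = 0.0673) or replicate 4 (adjusted p = 0.0829).

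**Figure D1:**
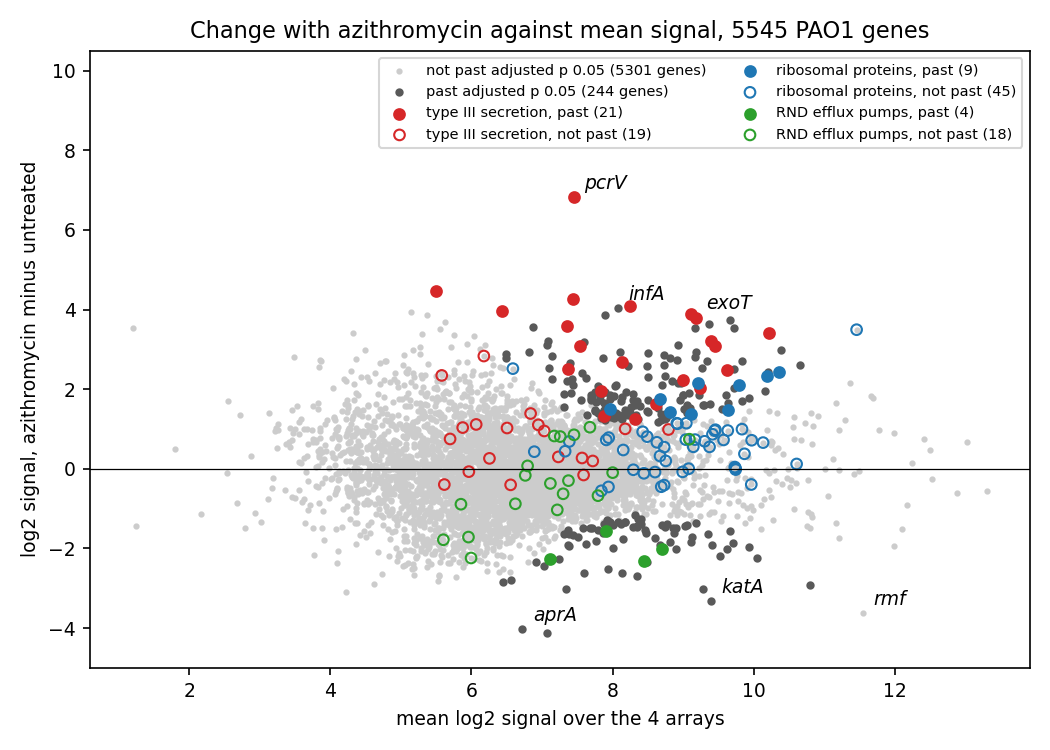
Each point is a PAO1 gene, with the mean log2 signal over the 4 arrays on the x axis and the log2 difference, azithromycin minus untreated, on the y axis; filled points of 3 gene lists passed adjusted p 0.05. The 21 type III secretion genes past the test lie above 0 and the 4 RND efflux genes past it lie below.

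Ribosomal protein genes lay 0.84 log2 units above the median of all genes (camera adjusted p = 8.85e-11). The adjusted p = 0.835 with an estimated correlation. Of 54 members 9 rose and 0 fell, 15 rose and 0 fell adjusted over the list alone, and 21 rises and 0 falls had an unadjusted limma p under 0.05. The 3 with the smallest p were rplC (log2 2.15 ± 0.40, adjusted p = 0.00108), rplS (1.75 ± 0.33, adjusted p = 0.00156) and rpsB (2.11 ± 0.47, adjusted p = 0.00682). The others were rpmA, rpmB, rplD, rplI, rpsF and PA4672. PA4672 encodes peptidyl-tRNA hydrolase and was listed by mistake for its neighbour PA4671, encoding ribosomal protein L25, which also rose (1.86 ± 0.42, adjusted p = 0.00754). With PA4671 in its place, chosen after seeing the data, again 9 of 54 members rose (camera adjusted p = 7.99e-11, and 0.833 with an estimated correlation). Leaving out untreated replicate 2 ended the list's call (adjusted p = 0.0825) with 2 members past the test. The shift of the list was 0.39 without that array, 0.51 without azithromycin replicate 4, 1.29 without untreated replicate 1 and 1.03 without azithromycin replicate 3. Leaving out azithromycin replicate 3 or replicate 4 left 1 member each, and median centring left 2. The 16S rRNA probe set had a signal of 40126 ± 7113 (SD) in untreated and 26699 ± 17276 in azithromycin cultures, with azithromycin replicate 3 lowest at 14482.

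Of 11 measured translation factors and ribosome-associated proteins, infA (signal 76.3 ± 51.9, 1 of the 2 arrays at control level, against 1103 ± 135, log2 4.04 ± 0.40, adjusted p = 4.32e-07) and efp, encoding elongation factor P (1.71 ± 0.38), rose. The list did not pass (camera adjusted p = 0.657). Adjusted over the list alone, 2 members rose and 3 fell. The gene rmf, for a ribosome-inactivating factor of stationary phase, had a signal of 10735 ± 3383 in untreated and 890 ± 365 in azithromycin cultures. Its difference of log2 -3.62 ± 1.35 did not pass (adjusted p = 0.171) as deposited and passed after quantile normalization (adjusted p = 4.58e-07). It was chosen after its values were seen.

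Among 8 regulators and autoinducer synthases of quorum sensing, lasR (log2 -1.75 ± 0.34, adjusted p = 0.00173) and lasI (-1.33 ± 0.36, adjusted p = 0.0278) fell and 0 rose, with the same counts adjusted over the list alone. The list's median lay 0.81 log2 units above that of all genes, with positive differences in 5 of 8 members. It did not pass the test for a common direction (camera adjusted p = 0.850), while fry's test for change in either direction gave adjusted p = 0.0135. Other lists passed that fry test too, 11 of 25 in all. Signals of rhlI (0.90 ± 0.40, adjusted p = 0.30), rhlR (0.97 ± 0.55, adjusted p = 0.475) and rsaL, a repressor of lasI (1.15 ± 0.78, adjusted p = 0.584), did not pass the test. With the block for pairs of arrays of like spread these 3 passed as higher (limma adjusted p = 0.00716, 0.00582 and 0.00229). The prior of that fit had infinite degrees of freedom, so a gene's own spread did not enter. For rsaL the groups overlapped, with signals of 1873 and 692 in untreated and 1840 and 3464 in azithromycin cultures. The calls for lasR and lasI were lost under median centring (adjusted p = 0.105 for lasR and 0.346 for lasI). They were also lost without azithromycin replicate 3 (0.0751 and 0.236) and without replicate 4 (0.0758 and 0.10), and that of lasI without untreated replicate 1 (0.30).

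Of 20 genes for quorum-controlled exoproducts, 5 fell and 1 rose. The falls were aprA (signal 457 ± 233 against 34.0 ± 30.7, log2 -4.02 ± 0.72, adjusted p = 8.48e-04), lasA (5049 ± 1867 against 677 ± 287, -2.92 ± 0.79, adjusted p = 0.0297), rhlB for rhamnolipid synthesis (-2.20 ± 0.41), the chitinase gene chiC (-1.84 ± 0.37) and the lectin gene lecA (-1.39 ± 0.35, adjusted p = 0.0169). The hydrogen cyanide synthase gene hcnA rose (1.40 ± 0.34, adjusted p = 0.0139). The elastase gene lasB had signals of 2961 ± 386 and 2844 ± 602 (log2 -0.07 ± 1.29, adjusted p = 0.991). rhlA had log2 -1.14 ± 0.80 (adjusted p = 0.609), past the test after quantile normalization (adjusted p = 0.00148). The list as a whole missed the threshold (camera adjusted p = 0.0754), and 6 members fell and 2 rose adjusted over the list alone. With the block for pairs of arrays of like spread it passed (adjusted p = 8.63e-04), with 7 members lower and 2 higher. The list passed after quantile normalization (adjusted p = 9.77e-05), with the offset (0.0382), without untreated replicate 2 (0.0184) and without azithromycin replicate 4 (7.78e-04). Without untreated replicate 1 (adjusted p = 0.624) or azithromycin replicate 3 (0.932) it did not, and its median relative to all genes turned from -0.18 to 0.23 and 0.27. The call for aprA was lost without untreated replicate 1 (adjusted p = 0.320). Those for lasA and lecA were lost under median centring (0.360 and 0.309), without untreated replicate 1 (0.141 and 0.0740) and without azithromycin replicate 3 (0.385 and 0.226) or replicate 4 (0.467 and 0.0521).

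**Figure D2:**
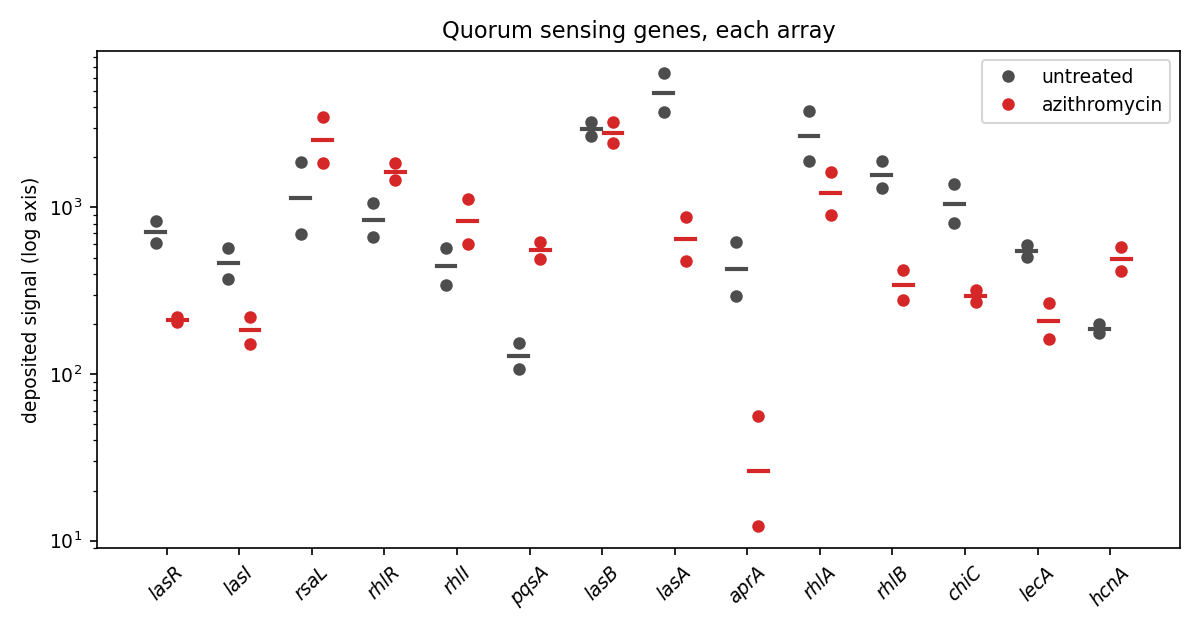
Deposited signal of 14 quorum sensing genes on a log axis, with a point per array and a bar at the geometric mean of each group (n = 2). Both azithromycin arrays lie below both untreated arrays for lasR, lasI, lasA, aprA, rhlA, rhlB, chiC and lecA, and the groups overlap for lasB and rsaL.

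PQS biosynthesis genes lay 0.51 log2 units above the median of all genes (camera adjusted p = 0.0133). The adjusted p = 0.726 with an estimated correlation. Of 9 members 3 rose and 0 fell, the same 3 and 0 adjusted over the list alone and at an unadjusted limma p under 0.05. They were pqsA (signal 130 ± 32.2 against 555 ± 91.9, log2 2.11 ± 0.35, adjusted p = 3.93e-04), phnA, encoding an anthranilate synthase subunit (signal 146 ± 5.52 against 441 ± 222, adjusted p = 0.0203), and pqsE (1.34 ± 0.36, adjusted p = 0.0264), whose product is not needed for making PQS. The list's call was lost without azithromycin replicate 4 (adjusted p = 0.211) and without untreated replicate 2 (adjusted p = 0.0825), as well as without genes under the 40th percentile of signal (adjusted p = 0.0762). Its shift was 0.12 and 0.17 log2 units without those arrays, 1.17 without untreated replicate 1 and 0.80 without azithromycin replicate 3. Of the 3 gene calls, median centring kept that of pqsA alone (limma adjusted p = 0.00930). Of 10 measured phenazine genes, phzM, encoding a pyocyanin methyltransferase, rose (log2 2.82 ± 0.59) and 0 fell, also adjusted over the list alone (camera adjusted p = 0.785).

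RND efflux pump genes lay at -0.52 log2 units relative to all genes (camera adjusted p = 0.0329). The adjusted p = 0.726 with an estimated correlation. The 4 of 22 members that fell, also 4 adjusted over the list alone, form the operon mexG (-2.31 ± 0.33, adjusted p = 4.78e-05), mexH (-2.02 ± 0.35, adjusted p = 5.21e-04), mexI (-2.27 ± 0.54, adjusted p = 0.0109) and opmD (-1.56 ± 0.36, adjusted p = 0.00951). PA2019, the mexX gene of a pump known to export macrolides, had log2 -0.30 ± 0.43 (adjusted p = 0.864). The list's call was lost under median centring (adjusted p = 0.0568) and without untreated replicate 1 (0.0800), untreated replicate 2 (0.0773) or azithromycin replicate 3 (0.107), where its shift was -0.29. Leaving out untreated replicate 1, azithromycin replicate 3 or azithromycin replicate 4 left 2 of its members past the test each.

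Genes of the TCA cycle lay at -0.60 log2 units relative to all genes (camera adjusted p = 0.0284). The adjusted p = 0.928 with an estimated correlation. Of 13 members 3 fell, 5 adjusted over the list alone: sucC (-1.65 ± 0.39, adjusted p = 0.0106), the aconitase gene acnB (-1.41 ± 0.38, adjusted p = 0.0277) and sucA (-1.49 ± 0.41, adjusted p = 0.0322). The list's call was lost under median centring (adjusted p = 0.0809) and without untreated replicate 1 (0.624) or azithromycin replicate 3 (0.905). Its shift turned to 0.03 without untreated replicate 1 and was -0.15 without azithromycin replicate 3, -1.05 without untreated replicate 2 and -1.03 without azithromycin replicate 4. The calls for sucC, acnB and sucA were lost without untreated replicate 1, azithromycin replicate 3 or azithromycin replicate 4, in adjusted p from 0.0505 to 0.334. Of 22 genes of NADH dehydrogenase and ATP synthase, nuoF, nuoG, nuoK and nuoN fell (log2 -1.45, -1.46, -1.53 and -2.34) and atpB rose (1.54). Median centring left 0 of these calls. The list did not pass (camera adjusted p = 0.0837), with 6 falls and 1 rise adjusted over the list alone. It passed after quantile normalization (adjusted p = 0.0230), without untreated replicate 2 (0.00294) and without azithromycin replicate 4 (9.16e-04). Without untreated replicate 1 (adjusted p = 0.706) or azithromycin replicate 3 (0.811) it did not, and its median relative to all genes turned from -0.11 to 0.37 and 0.23.

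Chaperone and protease genes lay at -0.61 log2 units relative to all genes (camera adjusted p = 0.0329). The adjusted p = 0.726 with an estimated correlation. Of 15 members, groEL fell (signal 817 ± 305 against 222 ± 101, log2 -1.91 ± 0.38, adjusted p = 0.00210), with 4 falls adjusted over the list alone. The cochaperonin gene groES had log2 -1.51 ± 0.54 (adjusted p = 0.138), past the test after quantile normalization (adjusted p = 9.68e-05), and ibpA had -1.16 ± 0.41 (adjusted p = 0.130). The list's call was lost under median centring (adjusted p = 0.0692) and without untreated replicate 1 (0.137) or azithromycin replicate 3 (0.411). That for groEL was lost under median centring (0.125) and without azithromycin replicate 3 (0.183). In the oxidative stress response, katA (signal 2209 ± 788 against 219 ± 67.0, log2 -3.32 ± 0.41, adjusted p = 7.04e-06) and the superoxide dismutase gene sodB (-2.01 ± 0.36) fell and the regulator gene oxyR rose (2.09 ± 0.42). These were 3 of 13 members, with 2 falls and 1 rise also adjusted over the list alone. The list did not pass (camera adjusted p = 0.0997) except after quantile normalization (0.0228) and with the block for pairs of arrays of like spread (0.00834). The call for sodB was lost under median centring (limma adjusted p = 0.0891).

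**Figure D3:**
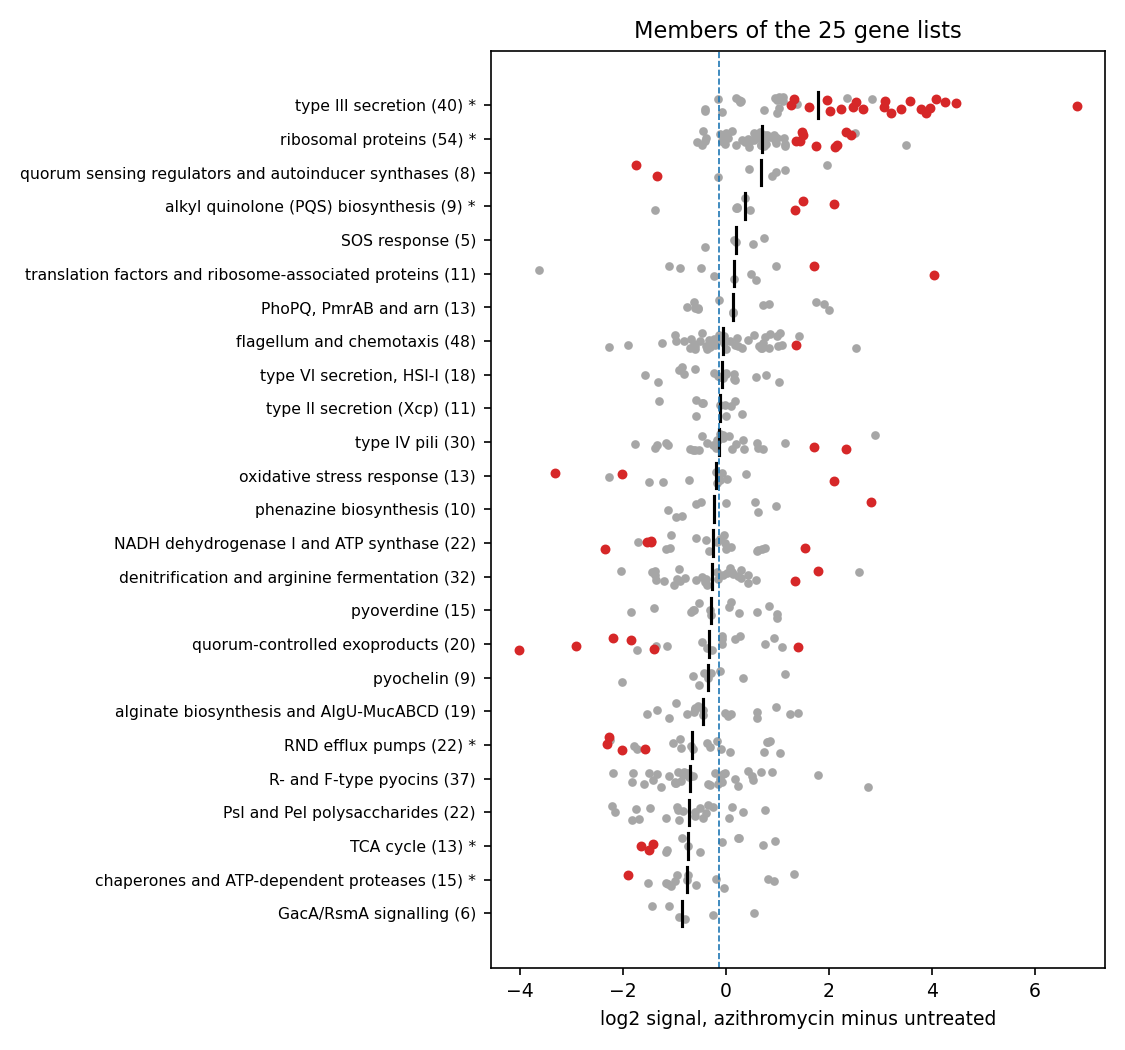
Each point is a measured member of a list (number in brackets), placed on the x axis by its log2 difference, azithromycin minus untreated; red points passed adjusted p 0.05, black bars are list medians, the dashed line is the median of all genes and an asterisk marks the 6 lists past the list test. With an estimated correlation 0 of these 6 passed (adjusted p from 0.726 to 0.928), and the type III secretion list has its median furthest to the right.

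In the other lists few genes passed. Of 30 type IV pilus genes, the pilin gene pilA (log2 2.33 ± 0.35, adjusted p = 7.86e-05) and pilH (1.72 ± 0.37) rose, 2 also adjusted over the list alone (camera adjusted p = 0.848). Of 48 flagellum and chemotaxis genes, the sigma factor gene fliA rose (1.37 ± 0.35), 1 also adjusted over the list alone (camera adjusted p = 0.692), and the flagellin gene fliC had -0.69 ± 0.95 (adjusted p = 0.859), past the test after quantile normalization (adjusted p = 0.0166). Of 32 denitrification and arginine fermentation genes, nirS (1.78 ± 0.42) and nirM (1.35 ± 0.39) rose, 2 also adjusted over the list alone (camera adjusted p = 0.785). For the flagellum, pilus and phenazine lists the median of members was below 0 while their mean and the test pointed up.

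In 10 lists with 155 measured members limma called 0 genes, over all genes and adjusted over the list alone, while 2 rises and 6 falls had an unadjusted p under 0.05. The camera adjusted p was 0.0754 for Psl and Pel polysaccharides, 0.110 for pyocins, 0.271 for Gac/Rsm signalling and 0.692 for alginate. It was 0.785 for the PhoPQ, PmrAB and arn genes, for Xcp secretion, for HSI-I, for the SOS response and for pyochelin, and 0.850 for pyoverdine. Quantile normalization brought the Gac/Rsm list past the threshold (adjusted p = 0.0389), median centring the Psl and Pel list (0.0426; 0.0398 by ranks) and leaving out genes under the 20th percentile of signal the pyocin list (0.0391). In these groups rpoS, the stationary-phase sigma factor gene, had a signal of 2654 ± 984 against 1218 ± 306 (log2 -1.09 ± 0.77, adjusted p = 0.610), past the test after quantile normalization (adjusted p = 0.00124). The alginate gene algD had log2 -1.34 ± 0.73 (adjusted p = 0.454).

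Outside the lists, the largest rises by the naming rule were PA2901 (log2 3.86 ± 0.45, adjusted p = 4.04e-06) and PA3371 (signal 227 ± 67.7 against 3296 ± 2041, 3.74 ± 0.47, adjusted p = 8.12e-06). The largest falls outside them were PA4078 (566 ± 20.0 against 64.0 ± 78.1, -4.14 ± 0.73, adjusted p = 7.44e-04), PA1244 (-3.03 ± 0.40), PA3415 (-3.02 ± 0.49), PA0587 (-2.83 ± 0.81), PA0565 (-2.80 ± 0.77), PA4377 (-2.70 ± 0.35) and PA0586 (-2.62 ± 0.36). Of the 10 largest falls, 4 had 1 azithromycin array at control level (PA4078, aprA, PA0587 and PA0565). Control level was 10.7 and 29.2 in the azithromycin arrays against 61.4 and 48.6 in the untreated arrays. This count is therefore not comparable with that for the rises, and does not show that the falls are better measured. The call for PA4078 was lost with the robust prior (adjusted p = 0.438), and those for PA0587 and PA0565 under median centring (0.0995 and 0.0946).

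In all, 244 of 5545 genes passed the limma test, 165 higher and 79 lower (67.6% higher), each by 2-fold or more, and 737 had an unadjusted p under 0.05. The groups did not overlap in 41.8% of genes, where chance gives 33.3%. Of 502 list members 44 rose and 21 fell, and 6 of 25 lists passed camera, 3 in each direction, 0 of them with an estimated correlation. The split of calls was 207 higher and 165 lower (55.6% higher) after quantile normalization and 75 higher and 11 lower (87.2%) after median centring. The median log2 difference of all genes was -0.13 as deposited, -0.06 after quantile normalization and 0.06 after centring. Fits without 1 array differ in their variance prior, which had infinite degrees of freedom without an untreated array. It had 7.93 without azithromycin replicate 3 and 10.3 without azithromycin replicate 4, so calls in these fits are not comparable. Without azithromycin replicate 3 limma called 81 genes, without azithromycin replicate 4 it called 50, without untreated replicate 1 173 and without untreated replicate 2 263. Of the 36 named genes past the test, 13 stayed past it without each array in turn: exoT, pcrH, PA3842, infA, PA2901, PA3371, katA, mexG, PA4078, PA1244, PA3415, PA4377 and PA0586. A variance prior without an intensity trend gave 0 genes, with 418 at an unadjusted p under 0.05 and a smallest adjusted p of 0.484, and kept the calls of the type III secretion and ribosomal lists alone. Leaving out genes under the 20th percentile of signal ended the calls of the RND efflux (adjusted p = 0.114), TCA (0.0849) and chaperone (0.0849) lists.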

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

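The block for pairs of arrays of like spread and the ribosomal list with PA4671 in place of PA4672 were chosen after the results were seen. In every setting the 244 genes past the test kept their sign where they were tested, and 240 of them passed after quantile normalization. For the other priors, the signal filters and the pair block the sign was fixed in advance, as these leave the log2 difference unchanged. Median centring shifts all genes alike, by less than the differences of these genes. Kept signs in those settings therefore show nothing about robustness. Over the named genes, 437 comparisons with an alternative kept direction and side of the threshold, 109 lost the call, 11 gained it and 3 turned sign; for the lists these were 323, 40, 14 and 21. The type III secretion list passed camera with its preset correlation in all 12 alternatives to the fit (adjusted p from 1.60e-47 to 1.08e-18) but not with an estimated correlation, the ribosomal list in 11, PQS in 8, chaperones and TCA in 6 each and RND pumps in 5. Camera does not use the robust prior, so for the lists that alternative repeated the main test. These tallies and the 323 kept list comparisons include that repeat, whose outcome was fixed in advance. With an estimated correlation 0 lists passed (adjusted p = 0.726 for type III secretion and 0.835 for ribosomal proteins). As that test has 2 degrees of freedom, its losses do not show that correlation explains the calls. Where a cause is not named, the cause was not tested.

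Quantile normalization called 372 genes, 165 of them lower, with 10 lists past the test. Median centring called 86, 75 higher and 11 lower, with 27 list members. Without genes under the 40th percentile 2 lists passed. Without an intensity trend limma called 0 genes, 0 higher and 0 lower (418 at an unadjusted p under 0.05), with 2 lists and 0 members. The pair block called 545 genes, 324 higher and 221 lower, with 120 members. Its variance prior had infinite degrees of freedom, so these counts are not comparable with those of the main fit. Of the lists, 0 passed by fry (11 in its test of either direction) and 3 by ranks. Those 3 were type III secretion, ribosomal proteins, and Psl and Pel polysaccharides. Camera on ranks ended the calls of PQS and chaperones (adjusted p = 0.0517 each), TCA (0.122) and RND pumps (0.129). Without each array in turn, calls ranged from 50 (azithromycin replicate 4) to 263 (untreated replicate 2), higher from 32 to 168, lower from 18 to 95, lists from 3 to 7 and members from 16 to 60. With 1 array fewer, the residual degrees of freedom fall too. The prior also changes, with infinite degrees of freedom without an untreated array and 7.93 or 10.3 without an azithromycin array. These counts therefore do not show which array matters most.

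The TCA list, past the test as deposited, kept the direction of its test in every fit, but its median relative to all genes turned from -0.60 to 0.03 without untreated replicate 1. The fitted sign of a gene or the test direction of a list turned as follows, in no case where it was past the test as deposited. lasB had log2 0.12 after median centring, which shifts all genes alike, and -0.29 to 0.15 without each array. The list adjusted p was 0.744 for phenazines after quantile normalization and 0.939 by fry, 0.962 for quorum regulators without genes under the 40th percentile, 0.924 for pyoverdine without a trend and 0.950 by ranks, 0.939 for type IV pili by ranks and 0.956 for translation factors by fry. Without each array the list adjusted p ran from 0.290 to 0.932 for PhoPQ and arn, 0.416 to 0.647 for quorum regulators, 0.624 to 0.965 for type IV pili, 0.633 to 0.957 for pyoverdine, 0.212 to 0.675 for pyochelin, 0.334 to 0.957 for Xcp, 0.316 to 0.672 for phenazines, 0.0610 to 0.957 for the flagellum, 0.137 to 0.965 for translation factors and 0.416 to 0.957 for HSI-I.

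No pairing by label was possible because the chips are numbered 1 to 4 once and the groups share no number. Keeping every probe set apart changes nothing, as each gene has 1, and the block by date was not run, as all arrays share 1 date. Control level covered 29.0% and 12.1% of genes in the untreated and 0.361% and 21.2% in the azithromycin arrays, which limits folds of dim genes.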

Other observations

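The tests here were chosen after the results were seen, except that of the 7 stationary-phase genes, and so were the genes described outside the naming rule. Genes next to each other on the chromosome often passed together. There were 26 runs of 2 or more neighbours past the test in the same direction, 8 of them with 3 or more genes, and 68 genes in all. The longest, with 8 genes from pcrG to exsB, belongs to type III secretion. Beyond the lists, trpG, trpD and trpC of tryptophan synthesis rose (mean log2 3.03), as did minC and minD of division site placement (3.04), fur, the iron uptake regulator, with omlA (2.52), and PA3369 to PA3371 (3.13). The pyruvate dehydrogenase genes aceE and aceF fell (-1.64). Adjacent pairs past the test in the same direction numbered 42, against a mean of 5.98 and a highest value of 15 in 10000 random placements of the calls.

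Of the 244 genes past the test, 36 stayed past it without each array in turn. Outside the naming rule they include trpG (log2 3.54 ± 0.38), htpX, a heat shock protease gene (3.12 ± 0.38), omlA (3.53 ± 0.43), adk, encoding adenylate kinase (2.58 ± 0.35), prs, encoding phosphoribosylpyrophosphate synthetase (2.91 ± 0.37), galU (2.16 ± 0.34), minD (2.53 ± 0.39) and the pilin gene pilA (2.33 ± 0.35). PA2564 (-2.53 ± 0.37) and PA2146 (-2.34 ± 0.34) were lower. Bacterioferritin genes bfrA (2.31 ± 0.36, adjusted p = 1.44e-04) and bfrB (2.17 ± 0.41, adjusted p = 0.00156) rose with all arrays. bfrA passed in 3 and bfrB in 2 of the 4 fits without 1 array. Among the intergenic probe sets limma called 0 of 199 and among those of other strains and structural RNA 0 of 138, with 8 and 7 at an unadjusted p under 0.05. For rRNA that fit could not have called a change, as the SE was 19.1 log2 units for 16S and 21.7 for 23S.

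Type III secretion genes were higher with azithromycin, with 21 of 40 past the test and a list call lost with an estimated correlation (adjusted p = 0.726), while the arrays differed in the spread of their signals. Untreated replicate 1 and azithromycin replicate 4 had interquartile ranges of log2 2.04 and 2.36, and untreated replicate 2 and azithromycin replicate 3 had 1.25 and 1.09. Within those pairs the list lay 2.47 and 1.55 log2 units above all genes, which argues against spread as the whole cause. With untreated signals raised to the highest control, the median fold of all members was log2 1.29, so signals near background may enlarge single folds but not account for the list. A response of the bacteria to azithromycin stays open as a hypothesis, found and tested on the same 4 arrays.

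Ribosomal protein genes were higher by camera with its preset correlation, a call lost with an estimated correlation (adjusted p = 0.835), beside lower signals of rmf and rpoS that did not pass as deposited. A difference in spread is argued against as the whole cause by shifts of 0.65 and 0.92 log2 units within the pairs of like spread. A candidate explanation is that azithromycin cultures were at an earlier physiological stage when sampled. Then 7 other stationary-phase genes (katE, osmC, osmE, cspD, PA0962, bolA and treA) should be lower; their median relative to all genes was -0.098, with 4 lower and 0 past the limma test (1 at an unadjusted p under 0.05). After quantile normalization osmC (log2 -0.98, limma adjusted p = 0.0321) and cspD (-0.81, adjusted p = 0.0499) passed as lower. The others did not pass: osmE (-0.55), PA0962 (-0.44) and treA (-0.29) were lower, katE (0.68) and bolA (0.98) higher. Stage and a direct effect of the drug on ribosomal genes cannot be told apart here. The median of -0.098 lies between the bounds set beforehand, and the design sampled 1 stage.

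The crossing of spread and group raises the question of exchanged chips. Over genes at or above the median signal, correlations within groups were 0.787 and 0.859 and between groups at most 0.579, a gap of 0.209, which argues against an exchange. Over all 5545 genes they were 0.720 and 0.772 against at most 0.686, a gap of the same sign but of only 0.034. Whether the hybridisation or the scaling of each array set the spread stays open. The median residual SD fell from 0.543 to 0.486 after quantile normalization (ratio 0.896), which decides nothing, since a common distribution lowers it whatever set the spread. No biological explanation was tested for it.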
